A study of Mus musculus with 4 samples.

How the data were processed

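Expression was measured in mucosa scraped from the colon of mice, 5 weeks of age, on an Affymetrix mouse array that holds 45101 probe sets. Each of 4 genotypes was represented by 1 array. The genotypes were Vhl floxed, Vhl deleted in the intestinal epithelium, and each of these with the Min mutation of Apc. The design text names 4 Vhl floxed mice, 3 Vhl deleted mice, 3 Vhl floxed mice with the Apc mutation and 5 Vhl deleted mice with the Apc mutation. It does not state whether the RNA of these mice was pooled for the arrays.

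The authors deposited log2 values, 1 per probe set and array, made with affy and RMA per the submitters' processing notes. RMA corrects the background, brings the arrays to one distribution by quantile normalization and summarises the probes of a probe set by median polish. Versions, and which arrays were normalized together, are not given in the sources used here. No value was missing. The medians of the 4 arrays were 6.06, 6.05, 6.06 and 6.07 on the log2 scale, in the order of the genotypes above. At equal rank the arrays differed by at most 0.14. Quantile normalization assumes that most transcripts keep their level, so a shift of the whole transcriptome would not be seen. The signal of dim probe sets is compressed by background, so differences near background understate the true fold. The 27 bacterial control probe sets lay between 2.82 and 5.10, with a median of 3.23.

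Gene names came from the platform annotation of GEO, which can be old, checked against the mouse RefSeq table of GRCm38.p6, which was used only for names and for the order of neighbouring genes. A single symbol was listed for 34958 probe sets, several for 932, and 9211 probe sets were not listed there. Entrez identifiers of 34754 probe sets were found in the RefSeq table, and 0 symbols changed. Probe sets with several symbols named no gene. This gave 18194 genes, of which 9012 had more than 1 probe set. Each gene took the probe set with the highest mean over the 4 arrays. A gene entered the comparisons when it reached a log2 value of 6 in at least 1 array, which left 11871 genes.

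With 1 array per genotype there is no replicate, so no p-value is given for any gene and the differences have no replicate check. The number of arrays limits the precision. Differences are log2 values of 1 array minus another. Genes at least 2-fold apart were counted in 4 comparisons, and in both comparisons of a kind. The pair of Vhl comparisons shared no array, nor did the pair of Apc comparisons. As the yardstick of spread that 4 arrays allow, the arrays were split into 2 and 2 in all 3 ways, and genes with a 2-fold difference between the mean values were counted. The crossed split holds no main effect of either genotype, only array noise, differences in sample makeup and any interaction.

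Before the data were examined, 36 gene lists were fixed. For each list the median log2 difference of the members above the floor was set against 10000 random lists matched on mean expression in 20 bins. A list was called apart under the 2.5th or over the 97.5th percentile. This describes these arrays and is no test across animals. The neutrophil list had 1 member above the floor and no percentile. Of the other 35 lists, 12 stood apart as higher and 6 as lower for Vhl deletion without the Apc mutation. With the Apc mutation 16 stood apart as higher and 5 as lower. The Apc mutation gave 5 higher and 13 lower with floxed Vhl, and 6 and 5 with deleted Vhl. Standing apart was thus common between these arrays. Genes named in the text followed a rule fixed at the same time. Per comparison, it took the 10 highest and 10 lowest genes. For Vhl it also took the 10 highest and 10 lowest by mean difference among genes at least 2-fold apart in both backgrounds. For the difference between backgrounds it took 5 and 5. Per list, it took the 5 members with the largest difference and any member at least 2-fold apart. Vhl, Apc, Hif1a, Epas1 and sex-linked genes were always included. Clone and predicted-gene symbols were passed over.

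The alternatives were no floor, a floor of 7, raising values under 6 to 6, the mean over a gene's probe sets, leaving out probe sets that can cross-hybridise, cyclic loess on top of the deposited values, and a 1.5-fold threshold. An additive limma fit of Vhl and Apc status was run for genes that differ in both backgrounds, with 1 residual degree of freedom and a Benjamini-Hochberg adjusted p threshold of 0.05. It treats arrays of different genotype as replicates and is no replicate check. Lists were also set against unmatched random lists and taken without members shared with other lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.

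The counting was tested on simulated arrays with the levels of the 11871 genes. Every gene was given the same normal noise, with the standard deviation of the crossed split, 0.18. For Vhl deletion in both backgrounds, 95 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3 were recovered, with 0 of 11671 unchanged genes called. In the measured crossed split 48 genes differed by at least 2-fold, which such noise would almost never give. The 0 calls therefore do not bound false calls in the measured arrays. For Vhl deletion without Apc mutation, 10 of 200 unchanged lists of 15 genes lay outside the random range, and 200 of 200 lists shifted by 0.5 did. The unchanged lists were random genes with independent noise, so their share outside was set by the percentiles used. It does not measure false calls for lists whose members vary together. In the additive limma fit for Vhl deletion in both backgrounds over 11871 simulated genes, 27 of 100 genes changed by 1, 91 of 100 changed by 2 and 5 of 11671 unchanged genes were called.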

Results

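The series compared the colon mucosa of mice that lacked Vhl in the intestinal epithelium with that of mice carrying floxed Vhl, each with and without the Min mutation of Apc. Vhl encodes the substrate receptor of the ubiquitin ligase that marks hypoxia-inducible factors (HIF) for degradation. Apc encodes a scaffold of the complex that degrades beta-catenin, and mice with the Min mutation develop intestinal adenomas. The comparisons address how loss of Vhl, alone or with mutant Apc, alters transcript levels in the colon. Each genotype was measured on 1 array, from groups of 3 to 5 mice in the design text, so no difference below has a replicate check. Values are deposited RMA log2 values, and a difference of 1 is a 2-fold difference.

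The targeted gene was lower in both arrays labelled Vhl deleted. Vhl read 8.40 in the Vhl floxed array and 7.04 in the Vhl deleted array, a difference of -1.36. With the Apc mutation it read 8.17 and 6.56, a difference of -1.61. Whether this probe set lies in the deleted part of the gene is not known here. The array's 4 control probe sets for Cre recombinase read 7.41 to 9.95 in the Vhl deleted arrays and 2.97 to 4.45 in the Vhl floxed arrays. Apc differed by 0.16 and 0.27 between Apc mutant and wild-type arrays, which does not check the labels because Min is a point mutation.

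Sex-linked, hepatocyte and clock transcripts also separated the arrays. Xist, the RNA that coats the inactive X chromosome, read 11.37 and 11.83 in the Vhl floxed arrays without and with the Apc mutation, and 5.58 and 6.25 in the Vhl deleted arrays. The Y-linked gene Eif2s3y read 8.58, 8.78, 7.27 and 8.80 in the Vhl floxed, Vhl deleted, Vhl floxed Apc mutant and Vhl deleted Apc mutant arrays. Xist followed Vhl status in both backgrounds, so sex makeup cannot be told apart from Vhl deletion in either Vhl comparison. Alb, the plasma protein albumin made in the liver, read 11.53 in the Vhl floxed array and 6.10 to 7.24 in the other arrays. The circadian clock list was lower in the Vhl deleted arrays, with medians of -0.49 and -0.54, and higher in the Apc mutant arrays, with medians of 0.41 and 0.30.

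**Figure D1:**
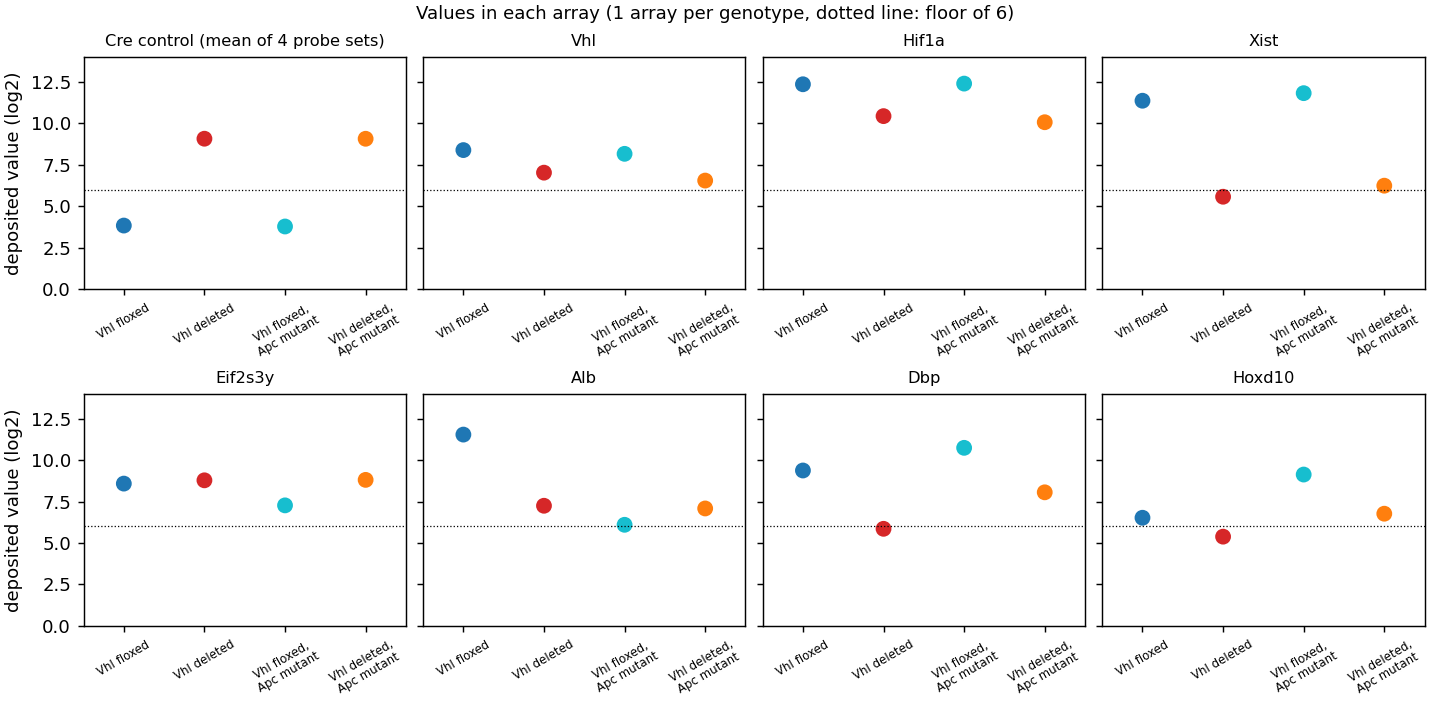
Deposited log2 values in each of the 4 arrays, with 1 point per array and a dotted line at the floor of 6. The Cre control and Xist separate the arrays by Vhl status, Alb is high in the Vhl floxed array at 11.53, and Hoxd10 is highest in the Vhl floxed, Apc mutant array at 9.13.

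In mice without the Apc mutation, Vhl deletion went with higher levels of hypoxia-responsive and glycolytic genes as groups. Slc11a2, the apical iron importer DMT1, was higher by 5.04. Ndufa4l2, a mitochondrial protein induced by HIF, was higher by 5.76, and Ankrd37, another hypoxia-induced gene, by 4.49. Mpp4, a scaffold protein best known from photoreceptors, was higher by 6.09, and Myl7, an atrial myosin light chain, by 5.69. Nrn1, Tmem237, Steap4, Dnase1l2 and Dmp1 completed the 10 highest genes, with differences between 4.16 and 5.00. Steap4 is a metalloreductase. Mpp4 and Dmp1 lay at background in the floxed array, so their folds are understated.

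The 10 lowest genes of this comparison were mostly hepatocyte genes. Serpina1c at -6.15, Alb at -4.29, Tdo2 at -3.87, Serpina1b at -3.69, Bhmt at -3.69, Cyp3a11 at -3.62 and Mup3 at -3.51 are genes known for high expression in hepatocytes, and were high in the Vhl floxed array alone. Serpina1b, Serpina1c and Mup3 belong to families of near-identical genes that the probes may not tell apart. Xist at -5.79, the clock output gene Dbp at -3.51 and Slc37a2, a sugar phosphate transporter, at -3.04 were the others. In all, 270 genes were at least 2-fold higher and 190 at least 2-fold lower of 11871. Without hepatocyte genes, left out after the data were seen, 157 were lower.

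In mice with the Apc mutation, the same comparison gave 335 genes at least 2-fold higher and 181 at least 2-fold lower. Nrn1 was higher by 6.44, Myl7 by 6.33, Ndufa4l2 by 5.52, Mpp4 by 5.39 and Slc11a2 by 5.17. Ak4, a mitochondrial adenylate kinase induced by hypoxia, was higher by 4.76 and Dnase1l2 by 4.61. Sptssb, a subunit of serine palmitoyltransferase, was higher by 7.02, Plet1 by 4.60 and the amino acid transporter subunit Slc3a1 by 4.58. Sptssb read 3.98 in the Vhl floxed, Apc mutant array and at least 10.18 in each other array, and Plet1 read 5.78 there and at least 9.58 in each other array. Slc3a1 read 7.46, 8.28, 4.87 and 9.45 in the Vhl floxed, Vhl deleted, Vhl floxed Apc mutant and Vhl deleted Apc mutant arrays. The lowest genes were Xist at -5.58, Slc37a2 at -3.88, Mptx1 at -3.08, S100g at -2.96, Scnn1g at -2.82, Dbp at -2.68, Wnt8b at -2.56, Cyp2f2 at -2.38, Hoxd10 at -2.36 and Hif1a at -2.33. Scnn1g is a subunit of the epithelial sodium channel and S100g the calcium carrier calbindin-D9k. S100g, Scnn1g, Wnt8b and Hoxd10 read 9.54, 9.33, 8.22 and 9.13 in the Vhl floxed, Apc mutant array. In the other arrays they read at most 7.28, 6.97, 6.54 and 6.77.

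Both backgrounds shared 187 genes at least 2-fold higher and 87 at least 2-fold lower with Vhl deletion. Independent lists of these sizes would share 7.62 and 2.90 genes. Across genes, which are not independent replicates, the Vhl differences of the 2 backgrounds had a Pearson r of 0.730 and a Spearman rho of 0.694. Ordered by the mean difference, the shared genes were led by Myl7 at 6.01, Mpp4 at 5.74, Nrn1 at 5.72, Ndufa4l2 at 5.64, Slc11a2 at 5.10, Tmem237 at 4.49, Dnase1l2 at 4.39, Ak4 at 4.38, Ankrd37 at 4.07 and Clca4b at 4.05. Mpp4 lay at background in both floxed arrays, so its mean difference is understated and its rank is not fixed. All 4 probe sets of Slc11a2 above the floor and all 3 of Ak4 lay higher in both backgrounds. Shared lower genes were led by Xist at -5.68, Slc37a2 at -3.46, Dbp at -3.10, Mptx1 at -2.87, Dpyd at -2.24, Cyp2f2 at -2.21, Cyp2c55 at -2.21, Hif1a at -2.12, Klb at -2.09 and Slc5a8 at -2.00. Xist marks the sex of the samples, and agreement between the backgrounds can also come from sex makeup, which followed Vhl status. The clock list, which holds Dbp, followed Vhl status too, with medians of -0.49 and -0.54. Time of day was not tested. Dpyd breaks down pyrimidines and Slc5a8 carries short-chain fatty acids. With either floxed array in place of the other, 136 and 134 genes were lower in both backgrounds. Both comparisons then share a control, so the 2.90 above does not apply to these counts. An additive limma fit, which treats arrays of different genotype as replicates, gave 432 genes higher and 270 lower at an adjusted p threshold of 0.05.

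**Figure D2:**
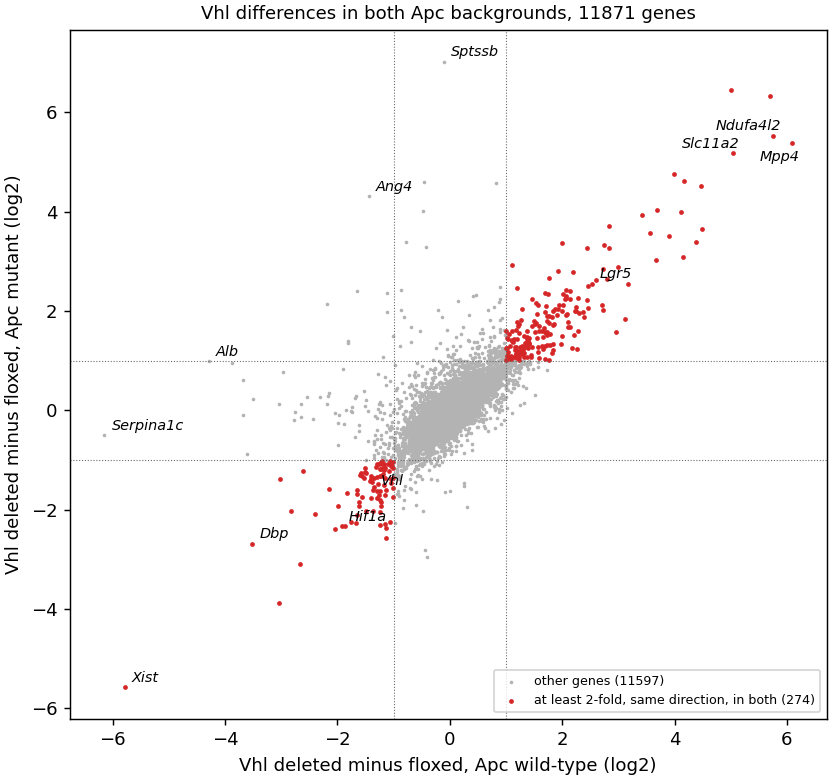
Vhl deleted minus floxed log2 difference per gene without the Apc mutation (horizontal axis) and with it (vertical axis), for 11871 genes. The 274 genes at least 2-fold apart in the same direction in both backgrounds are red, dotted lines mark 2-fold, and Alb, Ang4 and Sptssb lie away from the diagonal.

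Mean values split by Vhl status differed by at least 2-fold for 434 genes, against 45 genes when the arrays were split by Apc status and 48 in the crossed split. The standard deviation of the mean differences across genes was 0.45 by Vhl, 0.20 by Apc and 0.18 crossed. At a 1.5-fold threshold the Apc and crossed splits gave 144 and 132 genes, in the opposite order. Without hepatocyte genes the Apc and crossed splits gave 24 and 27 genes.

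HIF and hypoxia targets were higher as a group in both backgrounds. Of 31 measured above the floor, 14 were at least 2-fold higher and 1 lower without the Apc mutation, and 15 higher and 1 lower with it. The medians were 0.81 and 0.93, and each lay above all random lists. Egln3, the oxygen sensor that hydroxylates HIF, was higher by 3.67 and 3.03. Vegfa, the main angiogenic growth factor, was higher by 1.90 and 1.91, Adm, the vasodilator adrenomedullin, by 2.01 and 2.13, and Bnip3 by 2.37 and 1.98. Edn1, endothelin 1, was the lower member at -1.01 and -1.04. Among HIF pathway components, Hif1a was lower by 1.92 and 2.33, Hif3a was higher by 1.59 and 1.70, and Epas1, which encodes HIF-2 alpha, differed by -0.17 and -0.24. Of the 4 Hif1a probe sets 3 lay above the floor, and all 3 were at least 2-fold lower in both backgrounds. The list of components had medians of -0.06 and -0.07, inside the random range.

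Glycolysis genes had medians of 0.79 and 0.59, with 15 and 16 of 17 members higher. The lactate exporter Slc16a3 was higher by 2.73 and 2.85, Pfkp by 1.29 and 1.29, and Pfkl by 1.20 and 1.19. Oxidative phosphorylation genes had medians of -0.08 and -0.10, inside the random range, and Ndufa4 differed by -0.82 and -0.80.

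Iron genes did not stand apart as a list, with medians of 0.00 and -0.12 over 20 members, although 5 members were at least 2-fold higher in each background. Beside Slc11a2, the duodenal ferrireductase Cybrd1 was higher by 1.83 and 1.22. The metal transporter Slc39a14 was higher by 1.318 without and 1.504 with the Apc mutation. Ncoa4, the cargo receptor for ferritin degradation, was higher by 1.41 and 1.36. Hamp, the iron hormone hepcidin made mainly in the liver, was the lower member without the Apc mutation at -2.44. Like the hepatocyte genes, it was high in the Vhl floxed array alone, at 6.29. In the other arrays it read 3.78 to 3.95, at background, and with the Apc mutation it differed by -0.18. The median without the Apc mutation was 0.14 with the mean over probe sets, and it then lay above the random range. Without cross-hybridising probe sets the medians were 0.15 and 0.22, also above it.

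Proliferation genes were higher with Vhl deletion, with medians of 0.71 and 0.79 and 22 and 23 of 23 members higher. Bub1, a mitotic checkpoint kinase, was higher by 2.06 and 2.31, Rrm2, a ribonucleotide reductase subunit, by 1.00 and 1.59, and Aurka by 1.09 and 1.08. Inflammatory mediators had medians of 0.50 and 0.48 over 12 of 26 measured members above the floor. The prostaglandin enzymes Ptges and Ptgs2 were higher by 2.44 and 2.21 and by 1.76 and 1.76, and the cytokine Mif by 1.68 and 1.65. With the Apc mutation the inflammatory median was 0.22 at a floor of 7 and 0.15 with values under 6 raised to 6, both inside the random range. Xenobiotic and retinoid genes had medians of -0.46 and -0.25. Of 20 members, 6 were higher and 14 lower without the Apc mutation, and 8 higher and 12 lower with it. Cyp2c65 differed by -1.64 without and 2.40 with the Apc mutation. The efflux pump Abcb1a was lower by 1.99 and 1.92 and the sulfotransferase Sult1a1 by 1.38 and 1.45, while Cyp2s1 was higher by 1.93 and 2.04. In this list Cyp3a11 and Ugt2b5 are also hepatocyte genes high in the Vhl floxed array.

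Markers of other cell types also differed with Vhl deletion. All 15 endothelial markers were higher in both backgrounds, with medians of 1.14 and 0.93. Emcn was higher by 2.25 and 2.00, Flt1 by 1.46 and 1.69 and Plvap by 1.39 and 1.38. Macrophage and dendritic cell markers had medians of 0.82 and 0.42, MHC class II genes 0.82 and 0.75, and B and plasma cell markers 0.47 and 0.52. Of 11 B and plasma cell markers, 9 were higher and 2 lower without the Apc mutation, and 6 higher and 5 lower with it. Ms4a1 and Cd22 were among the lower in both backgrounds. The mast cell proteases Mcpt1 and Mcpt2, whose sequences are alike, were higher by 2.19 and 2.79 and by 2.07 and 2.25. Smooth muscle markers were lower, with medians of -0.51 and -0.39 and 0 of 15 members higher. Fibroblast markers had a median of 0.39 without the Apc mutation and 0.02 with it. Absorptive colonocyte markers lay inside the random range in both backgrounds, with medians of -0.07 and -0.04.

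Among markers of stem cells, Lgr5, a Wnt-driven receptor of R-spondins, was higher by 2.54 and 2.55. Of 11 members above the floor, 5 were higher and 6 lower in each background. Axin2 differed by 0.59 and 0.53, Rgmb by -0.93 and -0.70 and Smoc2 by -0.82 and -0.89, and the list medians were -0.16 and -0.30. With the Apc mutation the stem cell median was 0.16 when cross-hybridising probe sets were left out. Wnt targets had medians of -0.04 and 0.18, and with the Apc mutation the median was -0.11 at a floor of 7 and also -0.11 without members of other lists. Sox9, a transcription factor of crypt cells, differed by -1.22 without and -1.18 with the Apc mutation.

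**Figure D3:**
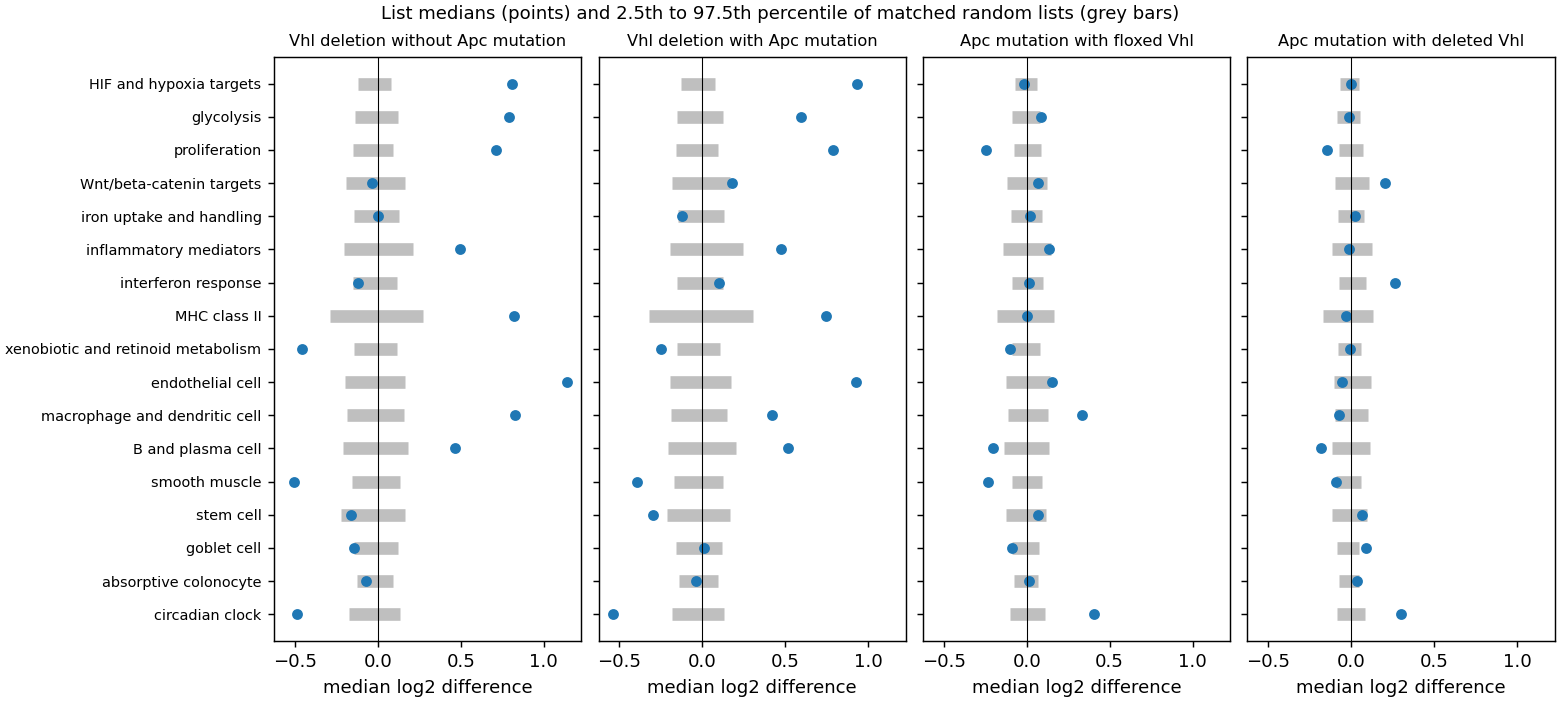
Median log2 difference of 17 fixed gene lists (points) in the 4 comparisons, with the range of matched random lists as grey bars, outside which a list was called apart. In both Vhl comparisons the HIF, glycolysis, proliferation and endothelial medians lie right of the bars, at 0.59 to 1.14, and the smooth muscle medians lie left of them.

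With floxed Vhl, the Apc mutation went with 14 genes at least 2-fold higher and 107 at least 2-fold lower. The higher genes were led by Hoxd10 at 2.60, Scnn1g at 2.36, S100g at 2.27, Hoxd11 at 2.02, Glycam1 at 2.00 and Hoxd13 at 1.95. Hoxd genes pattern the hindgut along its length, and Hoxd10, Hoxd11 and Hoxd13 were each highest in the Vhl floxed, Apc mutant array. The stretch of colon sampled cannot be told apart from genotype here and was not tested. Wnt8b was higher by 1.68, Ciart and Dbp, both clock genes, by 1.53 and 1.37, and Defb45 by 1.21. The lower genes were Sptssb at -6.30, the hepatocyte genes Serpina1c, Alb, Serpina1b, Cyp3a11, Tdo2 and Mup3 at -6.15 to -3.77, Plet1 at -4.26, and Reg3b and Retnlb, antimicrobial proteins of the epithelium, at -3.81 and -3.77. Without hepatocyte genes, 86 genes were at least 2-fold apart, against 121 with them. Proliferation genes had a median of -0.25, with 1 of 23 members higher, and Wnt targets a median of 0.07 inside the random range. Adipocyte markers had a median of -0.95, with 8 of 9 members lower, and small intestinal enterocyte markers one of -0.48, with 6 of 15 at least 2-fold lower. Macrophage and dendritic cell markers had a median of 0.34, and smooth muscle markers one of -0.23.

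With deleted Vhl, the Apc mutation went with 24 genes at least 2-fold higher and 14 at least 2-fold lower. Ang4, an antimicrobial ribonuclease, was higher by 2.49, the lipoprotein lipase Lpl by 2.41, Hsd17b13 by 2.35 and Dbp by 2.20. Zfp429, Prkg2, Mt4, B3gnt6, Slc51a and Cited1 were higher by 1.48 to 1.86. Apoa4 at -2.90, Reg3b at -2.14, Slc37a2 at -1.57, the immunoglobulin kappa entry Igk at -1.55, Apoc3 at -1.53 and the clock gene Arntl at -1.41 were lowest, followed by Cyp3a11, Mmp3, Apoa1 and Reg3g at -1.36 to -1.33. Apoa1, Apoa4 and Apoc3 are apolipoproteins of liver and small intestine. Of 3 Igk probe sets above the floor, 2 shared this direction. Wnt targets had a median of 0.20 above all random lists, with no member at least 2-fold apart, and Cdx2 and Mmp7 differed by 0.64 and 0.49. Standing apart was common in this comparison, with 6 of 35 lists higher and 5 lower, the clock list among the higher. Interferon response genes had a median of 0.26, with Ifit1 higher by 1.17. Neuron and glia markers had a median of -0.43, with 8 of 9 members lower, and one of -0.28 with floxed Vhl. Proliferation genes had a median of -0.14.

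The Apc differences of the 2 Vhl backgrounds shared 2 genes at least 2-fold higher, Dbp and Hoxd10, and 7 lower. Independent lists of these sizes would share 0.028 and 0.126 genes. Across genes their Pearson r was 0.114 and their Spearman rho 0.223. The additive limma fit, with 1 residual degree of freedom, gave 0 genes for the Apc mutation at the adjusted p threshold of 0.05. The genes lower in both included Reg3b at -3.81 and -2.14, Reg3g at -2.28 and -1.33, Apoa1 at -3.46 and -1.34 and Cyp3a11 at -4.10 and -1.36.

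The signed Vhl difference was higher with the Apc mutation than without it by at least 1 for 113 genes with a 2-fold Vhl difference in either background, and lower by at least 1 for 28. The highest were Sptssb, Ang4, Serpina1c, Alb and Plet1 and the lowest S100g, Scnn1g, Glycam1, Apoa4 and Fxyd4. Fxyd4 differed by 0.01 without and -1.62 with the Apc mutation. With 1 array per genotype, these values hold array noise and sample makeup as well as any interaction, and they were not tested.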

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

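The tests of liver RNA over 19 genes and of an array-wide shift were set before their results were seen. The other tests in this part, and the share over 15 genes, were chosen after the values were seen.

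Some genes differed by at least 2-fold in opposite directions between the backgrounds, and the difference was not tested because each genotype has 1 array. The Vhl difference with the Apc mutation exceeded that without it by 5.74 for Ang4, 4.32 for B3gnt6, 4.04 for Cyp2c65, 3.48 for B4galnt1, 3.21 for Arg1, 3.16 for Cyp2e1, 3.10 for Cmah, 2.49 for Alpi and 2.26 for Tmigd1. The Apc difference with deleted Vhl exceeded that with floxed Vhl by 4.16 for Hsd17b13, 3.76 for Slc3a1, 3.74 for Ugt2b5, 3.72 for Lpl and 3.29 for Prkg2. Ugt2b5 read 6.13 in the Vhl floxed array, where hepatocyte genes were high. It read 3.16 in the Vhl deleted and 4.32 in the Vhl deleted, Apc mutant array, so its higher value there lies at background. Arg1 and Cyp2e1 are hepatocyte genes too. For Vhl deletion they differed by -1.815 and -1.803 without the Apc mutation, the direction of the hepatocyte genes there, and by 1.39 and 1.35 with it. Arg1, B4galnt1, Cmah, Cyp2e1 and Tmigd1 fall outside the rule for named genes and were chosen after their values were seen.

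Signal was found in control probe sets that the comparisons do not use. The 4 Cre probe sets were higher in the Vhl deleted arrays by at least 4.70, 4.42, 5.53 and 5.84 in either background. Cre is also among the transcripts that can be added at hybridisation, but the 14 control probe sets for bioB, bioC and bioD differed by at most 0.46 between the same arrays.

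Hepatocyte transcripts were high in the Vhl floxed array. A first list of 43 hepatocyte genes was drawn up after some had been seen, and 37 lay above the floor. Their median difference was -2.05 for Vhl deletion without the Apc mutation and -2.28 for the Apc mutation with floxed Vhl. Of the 43 members 6 are in other lists, and 17 also passed the floor in another array. The rest of the 37 passed it through the Vhl floxed array alone. They are highest there by construction, so these medians are no support for liver RNA. In a second hepatocyte list of 68 genes, 19 lay above the floor. The same medians were -0.23 and -0.12 there, with 5 and 4 of the 19 genes at least 2-fold lower. Of these 19 genes 68.4% were highest in the Vhl floxed array, where matched genes gave 25.04%; quantile normalization fixes that share near chance, so it does not bear on a shift of the whole array. Because 4 of them passed the floor through that array alone, the other 15 were also counted, and 9 were highest there, above the random range of matched lists (mean 23.98%, upper end 46.67%) but not over the share set beforehand, so liver RNA stays open, as does small intestinal RNA with 50.0% of 12 genes in no hepatocyte list. No liver array was used here, and a biological difference of this genotype is untested.

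Hif1a was lower in both Vhl deleted arrays. A single faulty probe set is argued against, since the smallest of the differences over 3 probe sets was -1.88. A fall of epithelial cells by about the Hif1a difference is argued against by 19 epithelial genes, whose lower median was 0.035. Removal of Hif1a as well as Vhl in the epithelium cannot be told apart from regulation of the transcript, because genes driven mainly by HIF-1 had a median of at least 0.69 and HIF-2 may drive them too.

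Endothelial markers were higher in both Vhl deleted arrays. The higher of the smooth muscle medians was -0.39, which argues only against a rise of all other cell types alike. Macrophage and dendritic cell markers were higher too, with medians of 0.82 and 0.42. The 19 epithelial genes had medians of 0.035 and 0.071, inside the random range, which argues against a large fall of the epithelial share. A small fall together with less muscle cannot be told apart here. The 6 markers taken as HIF-responsive do not account for the whole endothelial difference, since the other 9 markers kept a median of at least 0.73. Whether those 9 also respond to HIF was not tested, so a HIF response among the markers is not excluded. A larger endothelial share with Vhl deletion stays open as a hypothesis and was not tested. Scraping depth, the stretch of colon sampled, litter, sex and time of day were not tested either.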

How the results depend on the processing

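Leaving out hepatocyte genes and exchanging a floxed array were chosen after the data were seen. Counts of genes at least 2-fold apart stayed within 1.5 times of the reported count in 93 combinations of count and setting and moved further in 22. At the 1.5-fold threshold, by construction, Vhl deletion gave 738 genes higher and 603 lower without the Apc mutation, 854 and 611 with it, and 525 and 324 in both backgrounds. The Apc mutation gave 405 genes with floxed Vhl, 180 with deleted Vhl and 36 in both. The splits gave 1284 by Vhl, 144 by Apc and 132 crossed, and the difference of the Vhl differences 466. With values under 6 raised to 6, the Apc and crossed splits gave 27 and 31 genes, and without hepatocyte genes 24 and 27. With the Vhl floxed array replaced by the Vhl floxed, Apc mutant array, 136 genes were lower in both backgrounds, and 134 with the opposite exchange; both comparisons then share a control. The additive limma fit gave 432 genes higher and 270 lower with Vhl deletion and 0 with the Apc mutation, at an adjusted p threshold of 0.05; with Apc, 1110 genes passed that threshold unadjusted.

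The iron list without the Apc mutation had a median of 0.14 with the mean over probe sets, and 0.15 when cross-hybridising probe sets were left out. With the Apc mutation it was 0.22 in that last setting; all of these lay above the random range. The inflammatory list with the Apc mutation fell inside the random range at 0.22 with a floor of 7 and 0.15 with values raised to 6, where fewer members carry signal. Changes of sign with the Apc mutation occurred for Wnt targets, at -0.11 with a floor of 7 and -0.11 without members of other lists, and for stem cell genes, at 0.16 without cross-hybridising probe sets. The cause was not tested. HIF target, glycolysis and proliferation medians kept their direction and side of the threshold in both Vhl comparisons under all planned settings. Of all list results 1008 kept their call, 29 gained it, 48 lost it and 3 changed sign. Signal over background limits genes near the bacterial controls, which reach 5.10.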

Other observations

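The tests of adjacent genes and of RNA of both sexes were chosen after the values were seen.

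In the Vhl deleted arrays the clock genes Per3, Nr1d1 and Nr1d2 were lower by 1.60, 1.15 and 1.35 without the Apc mutation, and Npas2 was higher by 1.51. With the Apc mutation Per3, Nr1d1 and Nr1d2 differed by -1.30, -1.70 and -0.89, and Npas2 by 1.58. Cck, an enteroendocrine hormone, was higher by 3.43 and 3.93, while the enteroendocrine list had medians of -0.07 and -0.06. The neuron and glia list had medians of -0.19 and -0.51, and the adipocyte list -0.09 and 0.58. The only neutrophil marker above the floor, S100a8, was higher by 1.71 and 1.55.

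Some lists stood apart with Vhl deletion in 1 background. Antimicrobial and acute phase genes had medians of 0.04 without and 0.71 with the Apc mutation, tuft cell markers -0.68 and 0.01, small intestinal enterocyte markers -0.39 and -0.12, and goblet cell markers -0.15 and 0.01. The difference between backgrounds was not tested. Genes of the integrated stress and unfolded protein response had medians of 0.15 and 0.23, and immediate early and heat shock genes 0.15 and 0.37, apart in both backgrounds.

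Among the 187 genes higher in both Vhl comparisons, 12 adjacent pairs were found, against a mean of 2.94 and a highest value of 12 in 10000 random placements. Without pairs that share a symbol stem, as gene families do, and without the pair of Tmem237 and Mpp4 that prompted the test, 7 remained, against a mean of 2.82, and 229 of 10000 placements gave as many. The others include Ndufa4l2 with Shmt2. Shmt2 was chosen after its values were seen. Whether neighbouring genes share a difference may be asked of other data, since all pairs had been seen before the test.

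Xist and Y-linked transcripts were found in the same arrays. The lowest value of a Y-linked gene in the Vhl floxed arrays was 6.35, and Xist was at least 11.37 there, which is consistent with RNA of both sexes in each of these samples.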
